A study of Mus musculus with 4 samples.

How the data were processed

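Single-cell RNA sequencing was done on 4 mouse medulloblastomas taken at postnatal day 21. Of these, 2 came from control animals, in which Math1-Cre switches on SmoM2, an active form of the SHH pathway receptor Smoothened, in the granule neuron lineage, and 2 came from animals that also carried floxed Piezo2 alleles. The labels call the libraries of a genotype biological replicates and state no pairing between genotypes. Tumours were dissociated with papain, about 5000 cells were loaded per library on the 10x Genomics v3 3' chemistry, and about 25000 reads per cell were sought, per the labels. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell, which the authors made with Cell Ranger on GRCm38 (mm10), per the submitters' processing notes; the Cell Ranger version is not given in the sources used here. The matrices list 32285 genes. Positions were taken from the GENCODE M21 annotation of GRCm38, which gave 32158 of these genes a position.

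The matrices held 9072 and 9551 barcodes for controls 1 and 2 and 9952 and 1228 for knockouts 1 and 2, 29803 in all. Barcodes with fewer than 500 genes or more than 15% mitochondrial UMIs were left out. Doublets were called per library with the Scrublet method of scanpy at an assumed rate of 0.008 per 1000 cells and removed. They made up 4.15% and 3.50% of the control cells and 4.56% and 0.528% of the knockout cells. The kept set of 27717 cells was made of 8460, 8931, 9195 and 1131 cells, with median depths of 6281.5, 5976, 6977 and 16297 UMIs per cell for control 1, control 2, knockout 1 and knockout 2. Knockout 2 therefore had the fewest cells and the deepest ones.

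Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and cells were clustered with 15 neighbours by the Leiden method at resolution 1, without integration of libraries, into 26 clusters. Clusters were named from 17 marker lists. A cell type outside the granule lineage needed at least 3 of its markers, and 50% of those measured, at 1 log2 unit or more above the other cells, with 20 CPM (counts scaled to a total of 1000000) added to both levels. Clusters left over were called tumour cells where at least 3 granule-lineage markers stood as far above the cells outside the lineage. They were neuron-like where 5 of the 10 granule neuron markers also stood that far above the rest of the lineage, and progenitor-like otherwise. The thresholds for names were set after the data were seen. A cluster led by haemoglobin genes stayed unnamed. It held 137, 100, 167 and 62 cells of the libraries in the order above, 1.37% ± 0.353 (SD, n = 2) of control cells and 3.65% ± 2.59 (SD, n = 2) of knockout cells. Class names are given as "like" because they rest on these markers alone.

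Cells were not treated as replicates. Raw UMI counts were summed per library and class, and the 2 control sums were compared with the 2 knockout sums by edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) after TMM scaling and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. A class needed 5 cells in every library to be tested. Endothelial-like cells numbered 3 in knockout 2, so their tests, and the tests that rest on them, were added after the data were seen. Log2 fold changes are knockout over control. Standard errors were derived from the fold change and the F statistic and are approximate. With 2 libraries per group the smallest p of a two-sided exact permutation test is 0.333, so a comparison of a single share could not pass 0.05. Shares of cells of a library have 95% Wilson intervals, CPM of single genes have exact Poisson intervals, and a count of 0 was given an upper limit of 3 counts. These intervals cover counting error only. Shares of cells with a UMI, and of cycling cells (2 or more UMIs over the 10 cycling markers), were computed after thinning each cell to 2000 UMIs.

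A set of 22 gene lists was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, where at least 5 members were measured. Members past the threshold are counted over all genes tested and adjusted over the list alone. The difference of the knockout effect between tumour and endothelial-like cells was tested as an interaction, with the library as a block.

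The gene lists, markers, rule for named genes, tests and main settings were fixed before the data were examined, except for the thresholds that name clusters, among them the 5 neuron markers, and the tests that rest on endothelial-like cells. In tumour and endothelial-like cells the rule took the 8 largest rises and the 8 largest falls among genes past the threshold that had a mean of at least 20 CPM in the higher group and every knockout library on the same side of every control library. Where fewer than 6 genes passed, it took the 10 smallest p-values at that level, as such and not as changed. It added Piezo2, the 2 members with the smallest p of up to 10 lists, a fixed set of genes of each tissue, and 3 genes each way in the other classes. Predicted gene models and mitochondrial, ribosomal protein and sex-linked marker genes were left out of the ranking. Members of lists that passed the threshold are named as well. The result of 1 gene that this rule named is not reported here.

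The count tests were checked on simulated libraries with the means and sizes of the real ones. Every gene of a class was given the same spread, the common value estimated for that class. The rates hold for that setting and do not cover genes whose spread is larger. For genes changed 2-fold, the test recovered 62.5% in tumour cells, 77.6% in progenitor-like, 82.0% in neuron-like, 11.8% in endothelial-like and 17.4% in astrocyte-like cells, 13.7% in microglia-like cells, 31.6% in oligodendrocyte precursor-like cells and 47.7% in oligodendrocyte-like cells. For genes changed 4-fold it recovered, in the same order, 97.0%, 98.0%, 100%, 65.9%, 82.0%, 78.7%, 87.2% and 94.6%. No simulated change was called in the wrong direction, and at most 15 unchanged genes were called, 15 of 4887 in oligodendrocyte-like cells. By camera at the preset correlation, a simulated list of 20 genes raised 1.5-fold was called in tumour and in endothelial-like cells, and 0 of 20 unchanged lists were. Camera with an estimated correlation and fry were not run on simulated lists. Both rest on 2 libraries per group here, so a list that they missed is not thereby shown to be unchanged. The simulated genes were drawn independently, so the false calls of camera on lists whose members move together were not checked.

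Alternatives were DESeq2 1.42.0, its size factors within edgeR, no low-count filter, replicate numbers as a block, each library left out, no filter or a strict filter on cells (at least 1000 genes and at most 5% mitochondrial UMIs), doublets kept, sums thinned to one total, equal numbers of cells, and Leiden resolutions of 0.5 and 2. Alternatives chosen after seeing the data kept the unnamed cluster with the tumour cells, set neuron-like cells by marker UMIs per cell, named neuron-like clusters from 6 of the 10 markers, and clustered tumour cells without the genes called in any tumour class. That clustering left 4 of the 10 neuron markers, so its clusters were neuron-like from 2 of the 4. Software also included Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9. Figures were drawn with matplotlib 3.10.9.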

Results

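The transcriptomes of single cells from SHH medulloblastomas of 2 control mice and 2 mice with floxed Piezo2, the gene of a cation channel opened by mechanical force, were compared at postnatal day 21. The design asks how loss of this channel in the tumour lineage changes the tumour cells and, from the title of the series, the tumour's blood vessels. Total UMIs were 63678974 in control 1, 63672311 in control 2, 76409100 in knockout 1 and 19834014 in knockout 2. Tumour cells of the granule lineage numbered 7822, 8213, 8420 and 1000 in the same order, and endothelial-like cells numbered 31, 40, 38 and 3. The tumour sums ran from 17995181 UMIs in knockout 2 to 64127889 in knockout 1. Sex is not in the labels. The Y-linked gene Ddx3y had 4849 UMIs in knockout 1 and 0 in the other 3 libraries, while the X-inactivation transcript Xist had 13 UMIs in knockout 1 and 125683, 148720 and 31675 in control 1, control 2 and knockout 2. The counts of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 49.8 between the controls and 38.5 between the knockouts over 15160 genes.

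Piezo2 (ENSMUSG00000041482, chromosome 18, 63010213 to 63387183, GRCm38) fell in tumour cells, from 2.85 ± 0.887 CPM in controls to 0.554 ± 0.0255 in knockouts (SD, n = 2 each), a 5.08-fold difference. The tumour cells held 186 and 120 Piezo2 UMIs in controls 1 and 2 and 37 and 10 in knockouts 1 and 2. As CPM over all UMIs these were 3.39 (95% exact Poisson interval 2.92 to 3.91) and 2.18 (1.81 to 2.61) in controls, against 0.577 (0.406 to 0.795) and 0.556 (0.266 to 1.02) in knockouts. All of these UMIs lay in progenitor-like cells, and neuron-like cells had 0 in every library. That count allows up to 0.257%, 0.252%, 0.0993% and 0.977% of neuron-like cells with a UMI in control 1, control 2, knockout 1 and knockout 2. The log2 fold change was -2.34 (SE 0.352) with an adjusted p of 0.0272 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Within progenitor-like cells it was -2.05 (SE 0.352), and the adjusted p was 0.0542.

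**Figure D1:**
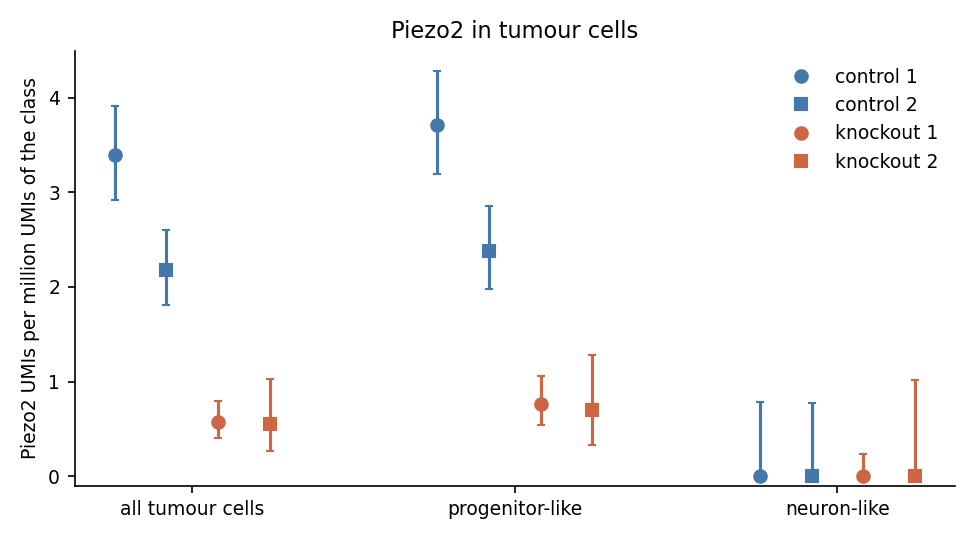
Piezo2 CPM over all UMIs in tumour cells and in the classes within them, 1 point per library with its 95% exact Poisson interval. In tumour cells the controls lie at 3.39 and 2.18 and the knockouts at 0.577 and 0.556.

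The share of tumour cells with a Piezo2 UMI, after thinning to 2000 UMIs per cell, was 0.711% and 0.309% in controls 1 and 2 and 0.182% and 0.203% in knockouts 1 and 2. Unthinned it was 2.20%, 1.27%, 0.428% and 0.900%. Cells shallower than 2000 UMIs left out of the thinned shares numbered 85, 117, 164 and 16. In microglia-like cells, which should lack the gene, 0 of 139, 1 of 216, 0 of 187 and 0 of 21 cells of control 1, control 2, knockout 1 and knockout 2 had a UMI. The cell in control 2 made 0.463% (95% Wilson interval 0.0818% to 2.58%), and the 0 counts allow up to 2.16%, 1.60% and 14.3%, so too few microglia-like cells were held to place the knockout tumour cells above or below this background. Neuron-like cells gave a closer limit. In knockout 1, progenitor-like cells held 0.768 CPM over all UMIs (95% exact Poisson interval 0.541 to 1.06), above the upper limit of 0.232 in neuron-like cells. In knockout 2 they held 0.696 (0.334 to 1.28), which overlaps the upper limit of 1.02 in neuron-like cells. The 0.900% of knockout 2 came from tumour cells with a median of 16793 UMIs. The exons removed by the floxed allele are not given in the sources used here, and a 3' tag outside them would not report the deletion. The adjusted p of Piezo2 was 0.0781 without knockout 1 and 0.0555 without knockout 2, with log2 fold changes of -2.42 and -2.31.

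Among genes at 20 CPM or more in the higher group, predicted gene models left out, Sox18, a transcription factor best known from vessel endothelium, rose most in knockout tumour cells, 6.78-fold, from 8.98 ± 1.81 to 60.4 ± 32.7 CPM (SD, n = 2 each). Insm1, a zinc finger factor that drives neuronal differentiation of progenitors, rose 3.24-fold, from 121 ± 8.76 to 391 ± 50.01. Rpa3, a subunit of the single-stranded DNA-binding complex RPA, rose 2.79-fold, and Camk2b, a calcium/calmodulin-dependent kinase of neurons, 2.67-fold. Apoo, a subunit of the complex that shapes mitochondrial cristae, fell from 55.3 ± 2.71 to 8.24 ± 0.894, and Rnf121, a ubiquitin ligase of the secretory pathway, fell from 141 ± 26.1 to 21.8 ± 1.78. Hes1, a Notch target that holds neural progenitors undifferentiated, fell from 183 ± 76.7 to 53.6 ± 7.36, and the stem cell factor Sox2 from 19.97 ± 3.98 to 9.15 ± 0.732. Apoo, Rnf121 and Hes1 also fell by 1 log2 unit or more in microglia-like cells (-1.96, -2.99 and -1.13), so these falls were not particular to tumour cells. The other genes named here did not move that far the same way there, or were not measured there.

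By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 559 of 15160 genes changed in tumour cells, 345 up and 214 down. Sox18 (ENSMUSG00000046470, chromosome 2, 181669836 to 181671640) had a log2 fold change of 2.76 (SE 0.361, adjusted p = 0.0230). Insm1 (ENSMUSG00000068154, chromosome 2, 146221921 to 146225020) had 1.69 (SE 0.127, adjusted p = 0.00481). Apoo (ENSMUSG00000079508, chromosome X, 94367117 to 94417093) had -2.73 (SE 0.128, adjusted p = 0.00145), and Rnf121 (ENSMUSG00000070426, chromosome 7, 102019137 to 102065469) had -2.70 (SE 0.155, adjusted p = 0.00263). Among genes that met the rule for named genes, with its limit of 20 CPM, the other large rises were those of Rpa3 (1.48), Mex3d (1.45), the noncoding host of a small nucleolar RNA Snhg6 (1.43), Camk2b (1.42), Papss1 (1.37), which makes the sulphate donor of the cell, and Irak1bp1 (1.32). The other large falls by that rule were those of the actinin-binding Pdlim3 (-2.21), the splicing factor Cwc22 (-1.92), the ceramide kinase Cerk (-1.83), Hes1 (-1.78), the kinase Mast4 (-1.69) and the glutathione transferase Mgst1 (-1.60). Of these rises and falls, those of Snhg6 and Cwc22 were also seen in microglia-like cells (1.91 and -1.86), as was that of Hes1. The SHH effector Gli1 fell by 0.59 on the log2 scale (adjusted p = 0.0439 by the same edgeR test) and Sox2 by 1.12 (adjusted p = 0.0291). Genes that did not pass were Atoh1 (0.27), Ptch1 (-0.12), Mki67 (-0.37), Neurod1 (0.10), Axin2 (-0.00), Ctnnb1 (0.19) and Vegfa (0.54), with adjusted p from 0.1098 for Mki67 to 0.999 for Axin2 by that test. Lef1 had 2, 6, 4 and 4 UMIs in the tumour cells of control 1, control 2, knockout 1 and knockout 2 and was not tested. The count of changed genes was 118 without knockout 1, 246 without knockout 2, 156 without the low-count filter, 296 with equal cell numbers and 1623 by DESeq2, of which 51.0% were up against 61.7% by edgeR. Without knockout 1 the falls of Hes1 and Pdlim3 missed the threshold, without knockout 2 that of Pdlim3 did, and those of Sox2 and Gli1 missed it without either knockout (Gli1 also without control 2), at -1.22 and -0.52 without knockout 1. Without the low-count filter all 4 missed it, Hes1 at an adjusted p of 0.0503 by edgeR.

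**Figure D2:**
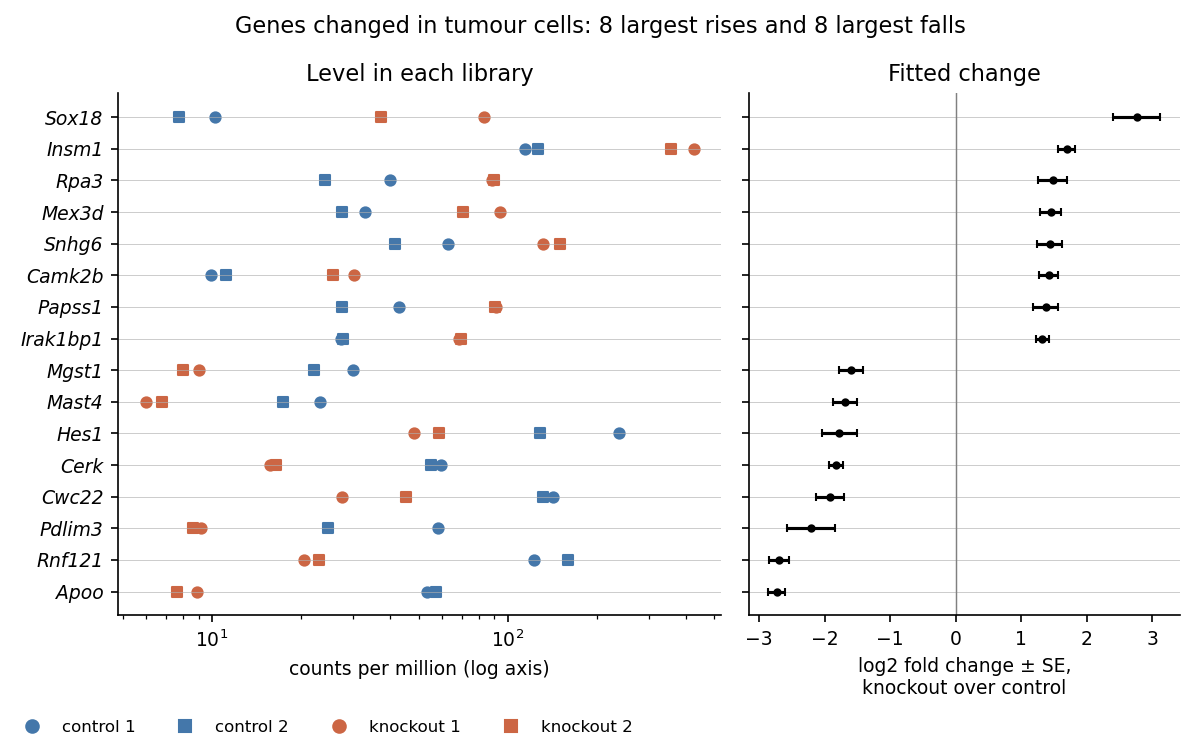
CPM in tumour cells of each library on a log axis, for the 8 largest rises and the 8 largest falls past the threshold at 20 CPM or more, 1 point per library, predicted gene models left out. Sox18 lies at 10.3 and 7.71 in controls and 83.5 and 37.2 in knockouts 1 and 2.

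Genes of granule neuron differentiation were higher in knockout tumour cells by camera (limma) at its preset correlation, but not with an estimated correlation (adjusted p = 0.680) or by fry (0.350), and knockout tumour cells also held a larger share of neuron-like cells by clusters. Of 28 measured members 24 were higher and 6 rose: Nrn1, a neurite outgrowth protein, 2.30-fold, the neuronal tubulin Tubb3 1.67-fold, the axonal adhesion protein Cntn2 1.54-fold, the calcium sensor Vsnl1 5.89-fold, and the GABA-A receptor subunits Gabrd 5.35-fold and Gabra6 6.52-fold, both of mature granule neurons. Most Vsnl1 and Gabra6 UMIs lay in cluster 24, which has these genes among its leading 10 and held 22, 29, 207 and 8 of the tumour cells of control 1, control 2, knockout 1 and knockout 2: 51, 44, 576 and 72 of the 69, 64, 655 and 77 Vsnl1 UMIs and 29, 34, 387 and 35 of the 31, 40, 416 and 35 Gabra6 UMIs. Of the 38, 34, 333 and 33 Gabrd UMIs it held 13, 17, 232 and 16. In the tumour cells outside cluster 24, Vsnl1 stood at 0.328, 0.364, 1.24 and 0.279 CPM over all UMIs in the same order. Gabra6 stood at 0.0365, 0.109, 0.457 and 0 there, so both were higher in knockout 1 alone. Gabrd stood at 0.456, 0.309, 1.59 and 0.948, higher in both knockouts. The markers used here do not tell tumour cells from normal granule neurons. The NMDA receptor subunit Grin2b moved against the list and fell, with a log2 fold change of -1.04 (SE 0.143). Adjusted over the list alone, 19 members passed. Genes of the G2M phase were lower in 43 of 52 measured members, of which Dlgap5, a spindle protein, fell by 0.55 on the log2 scale, none rose, and 14 passed when adjusted over the list alone. Genes of mural coverage and basement membrane were lower in 16 of 18: the collagens Col4a1 (-1.08), Col4a2 (-1.27) and Col18a1 (-0.72) and the fibronectin gene Fn1 (-1.08) fell, the potassium channel subunit Kcnj8 (1.18) rose, and 6 passed when adjusted over the list alone.

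Of 30 measured genes of actomyosin and cytoskeletal tension 24 were lower. Talin 1 (Tln1, -0.51) and filamin A (Flna, -0.68), which couple integrins and membranes to actin, fell, and 4 passed when adjusted over the list alone. YAP and TAZ target genes were lower in 18 of 22, but the only member past the threshold, the ectonucleotidase gene Nt5e (1.78), rose, and 5 passed when adjusted over the list alone. Of 18 genes of neural stem cells and quiescence 11 were lower. Hes1, Sox2 and the intermediate filament gene Nes (-1.19) fell, Id2 (0.54), an inhibitor of basic helix-loop-helix factors, rose, and 6 passed when adjusted over the list alone.

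In tumour cells these 6 of 22 lists were called by camera (limma) with its preset correlation and Benjamini-Hochberg adjustment: granule neuron differentiation up (adjusted p = 7.07e-08), and G2M phase (6.99e-06), mural coverage and basement membrane (2.41e-04), actomyosin (0.00206), YAP and TAZ targets (0.0403) and neural stem cells (0.0433) down. None held with an estimated correlation (adjusted p = 0.680 for each with an estimated correlation), and fry (limma) called 0 of the 22, the smallest adjusted p being 0.346. How often either would call a changed list in so few libraries was not checked, so these misses do not show that the lists were unchanged. YAP and TAZ targets lost the preset-correlation call without control 1 (adjusted p = 0.299), without knockout 1 (0.141) or without knockout 2 (0.09445), and neural stem cells lost it without knockout 2 (0.108).

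Among the 16 lists not called in tumour cells, S phase had 1 rise, Rrm2 (0.56), a subunit of the enzyme that makes deoxynucleotides, in 43 measured genes, and SHH targets had 1 fall, Gli1, in 12. The tip cell and angiogenesis list had the falls of Col4a1 and Col4a2 in 14, and endothelial barrier and transport had the rise of Sox18 in 24. Calcium handling had the rise of Camk2b and the fall of Nfatc4 (-1.86), a calcineurin-dependent factor, in 30. Hypoxia and glycolysis had the fall of Hk2 (-0.88) and the rise of Tpi1 (0.60), 2 glycolytic enzymes, in 20. The p53 and DNA damage list had the rise of Trp53inp1 (0.69) in 20, interferon and MHC class I that of H2-D1 (0.69) in 22, angiogenic ligands that of the chemokine Cxcl12 (0.98) in 20, and immediate early and dissociation stress those of Dusp1 (0.69) and Socs3 (1.18) in 25. Oxidative phosphorylation (28 measured), WNT targets (16), WNT ligands and modulators (15), endothelial leak and activation (11), cadherin and integrin adhesion (24) and mechanosensitive channels (13) had 0 genes past the threshold of edgeR's test. Adjusted over the list alone, the 16 lists held 6 in SHH targets, 5 in tip cells, 5 in calcium handling, 8 in endothelial barrier, 4 in angiogenic ligands, 4 in mechanosensitive channels, 3 in WNT ligands, 2 each in p53, endothelial leak, hypoxia and immediate early genes, 1 in interferon and 0 in the rest. The median, mean and test differed in sign for WNT ligands, immediate early genes, mechanosensitive channels and angiogenic ligands. Listed members with the smallest p that did not pass were Cdca8 (-0.52), Crim1 (-0.75), Ccnd1 (-0.47), Ung (0.48) and Mdm2 (0.64).

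**Figure D3:**
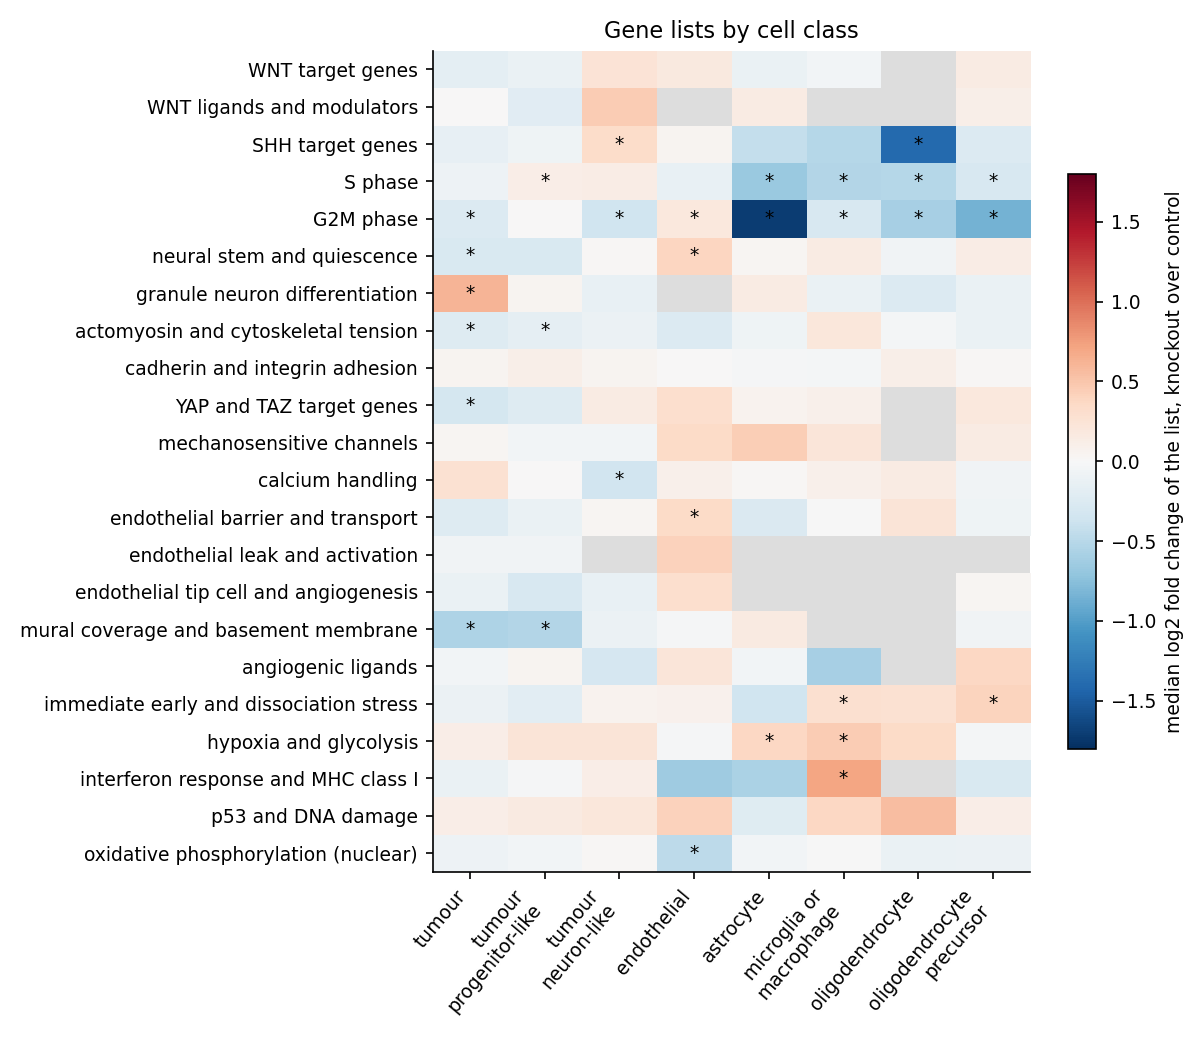
Median log2 fold change, knockout over control, of each gene list (vertical axis) in each cell class (horizontal axis), with the scale in the colour bar. Asterisks mark camera adjusted p below 0.05 at the preset correlation and grey marks fewer than 5 measured members; granule neuron differentiation stands at 0.62 in tumour cells.

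Progenitor-like and neuron-like tumour cells were also tested on their own. Progenitor-like cells came mostly from clusters 3 and 6 in knockout 1 and from clusters 1, 2, 5, 7, 8, 9 and 11 in the controls. In knockout 2, 143 and 42 of 693 progenitor-like cells lay in clusters 3 and 6, and most of the others in the clusters of the controls. Neuron-like cells came most often from cluster 15 in knockouts, which had 5 of the 10 neuron markers, and from clusters 13, 17 and 18 in controls, which had 7, 7 and 9. In progenitor-like cells, Insm1 rose 3.44-fold from 120 ± 8.31 to 411 ± 59.3 CPM, Sox18 6.53-fold and Rpa3 3.05-fold, and Grin2b fell from 20.5 ± 7.04 to 2.31 ± 0.0898 (SD, n = 2 each), with Apoo (-2.79) and Rnf121 (-2.73). The DNA replication genes Rrm2 (0.83) and Mcm2 (0.66) rose, as did Nt5e (1.83), Kcnj8 (1.44) and, 2.64-fold, Camk2b, and Col4a2 (-1.01) fell. In neuron-like cells, the progenitor factor Atoh1 rose 2.48-fold from 28.9 ± 2.05 to 71.1 ± 8.95 and the SHH target Mycn 2.05-fold, while Neurod1, which drives granule neuron differentiation, fell 1.92-fold from 1673 ± 122 to 875 ± 195. The growth cone gene Gap43 fell 1.74-fold, Grin2b 3.25-fold and Hes1 from 9.14 ± 1.65 to 0.742 ± 0.290. As the libraries fill these classes from different clusters, the values mix composition with change within a cell state. The gene and list tests of both classes share this limit, and the 2 cannot be told apart here.

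By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 146 of 14770 genes changed in progenitor-like cells (98 up, 48 down) and 477 of 11634 in neuron-like cells (274 up, 203 down). Of the tumour calls tested in both, 143 were called the same way in progenitor-like cells and 154 in neuron-like cells, which are parts of the same tumour cells. The largest rises in neuron-like cells were those of Sox18 (3.46), the muscle determination factor Myod1 (2.45) and the immediate early gene Fosb (1.85), and the largest falls at 20 CPM, predicted gene models left out, were those of Apoo (-2.48), Cwc22 (-2.29) and Rnf121 (-1.96). The adhesion gene L1cam (-1.14), the potassium channel gene Kcnk2 (-1.03), the talin gene Tln1 (-0.63) and the calcium genes Cacna1e (-0.75), Cacna1a (-0.59) and Calm2 (-0.59) fell, and Mcm2 (1.45), Mcm5 (0.95), Hjurp (0.97), Msi1 (0.68), Wnt4 (1.41), Ntn1 (0.84), Cdh4 (0.84), Nr4a1 (1.47), Pkm (0.62), Trp53inp1 (0.76), Nrn1 (0.87) and Vsnl1 (1.31) rose. Camera with its preset correlation called S phase up (adjusted p = 0.0190) and actomyosin (0.0190) and mural coverage (0.0188) down in progenitor-like cells, and SHH targets up (0.0368) and G2M phase (2.87e-04) and calcium handling (0.00698) down in neuron-like cells. None of these 6 lists held with an estimated correlation, with an adjusted p of 0.930 for each in progenitor-like and 0.670 for each in neuron-like cells. Kcnj8 and Hjurp rose against the direction of mural coverage and of G2M phase. Adjusted over the list alone, 6, 4 and 6 members passed in progenitor-like cells and 4, 11 and 8 in neuron-like cells, in the order given. Fry called 1 list in neuron-like cells, endothelial barrier and transport (adjusted p = 0.0221 by limma), in which 1 of 15 measured genes, Sox18, passed and 9 were higher. The count in progenitor-like cells was 2 without knockout 1, 21 without knockout 2, 534 without control 1, 307 without control 2, 463 without the low-count filter, 313 with equal cell numbers and 991 by DESeq2, of which 56.9% were up against 67.1% by edgeR. In neuron-like cells it was 131 without control 2, 175 without knockout 1, 130 under the strict cell filter, 1444 without the low-count filter and, by edgeR, 0 without knockout 2, where 1699 genes had an unadjusted p below 0.05; DESeq2 gave 467 with all libraries.

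The states of the tumour cells were compared as shares of cells. Neuron-like cells, named from genes such as Neurod1, Tubb3 and Cntn2, made up 14.7% ± 0.313 of control and 33.3% ± 3.66 of knockout tumour cells (SD, n = 2 each), with 14.9% and 14.5% in controls 1 and 2 and 35.9% and 30.7% in knockouts 1 and 2. Clustered again without the genes called in any tumour class, and named from 2 or more of the 4 neuron markers then left, the shares were 20.2% ± 2.85 and 31.6% ± 0.157, a difference of 11.4 points against 18.6, and by neuron marker UMIs per cell the difference was 12.6 points. Most of the difference of 18.6 points lay in cluster 15, with 79, 17, 1734 and 147 cells of control 1, control 2, knockout 1 and knockout 2 and 5 neuron markers, the fewest that the naming rule took. Named from 6 or more markers, neuron-like cells made up 14.1% ± 0.255 and 15.6% ± 0.506, a difference of 1.54 points. Both the limit of 5 and that of 6 were set after the data were seen. Cycling tumour cells, with UMIs of genes such as Mki67 and Top2a, made up 43.6% ± 3.20 of controls and 39.1% ± 0.704 of knockouts after thinning to 2000 UMIs. Unthinned, the difference of -4.45 points turned to 1.13. Cycling progenitor-like cells made up 47.2% and 52.7% in controls 1 and 2 and 57.3% and 55.1% in knockouts 1 and 2. These shares depend on the naming of cluster 15, whose mostly knockout cells leave the progenitor-like class. Few neuron-like cells cycled: 2.79%, 4.09%, 3.88% and 4.10% in control 1, control 2, knockout 1 and knockout 2. The higher share in knockouts therefore does not show that progenitors cycled more.

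The two-sided exact permutation p was 0.333 for the neuron-like share and 0.333 for the cycling share, the smallest that 2 against 2 libraries can give. Tested as cell counts by edgeR with Benjamini-Hochberg adjustment over 11 classes, neuron-like tumour cells had a log2 fold change of 1.15 and an adjusted p of 0.112, and 0 classes passed, with 1 at an unadjusted p below 0.05. Neuron-like cells passed at Leiden resolution 0.5 (adjusted p = 0.0372 by edgeR) and under the strict cell filter (0.0147), where oligodendrocyte precursor-like cells passed too (0.0159). Endothelial-like cells made up 0.407% ± 0.0576 of control cells and 0.339% ± 0.105 of knockout cells, oligodendrocyte-like cells 0.405% ± 0.155 and 0.724% ± 0.101, and oligodendrocyte precursor-like cells 2.38% ± 0.0794 and 1.85% ± 0.378 (SD, n = 2 each).

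**Figure D4:**
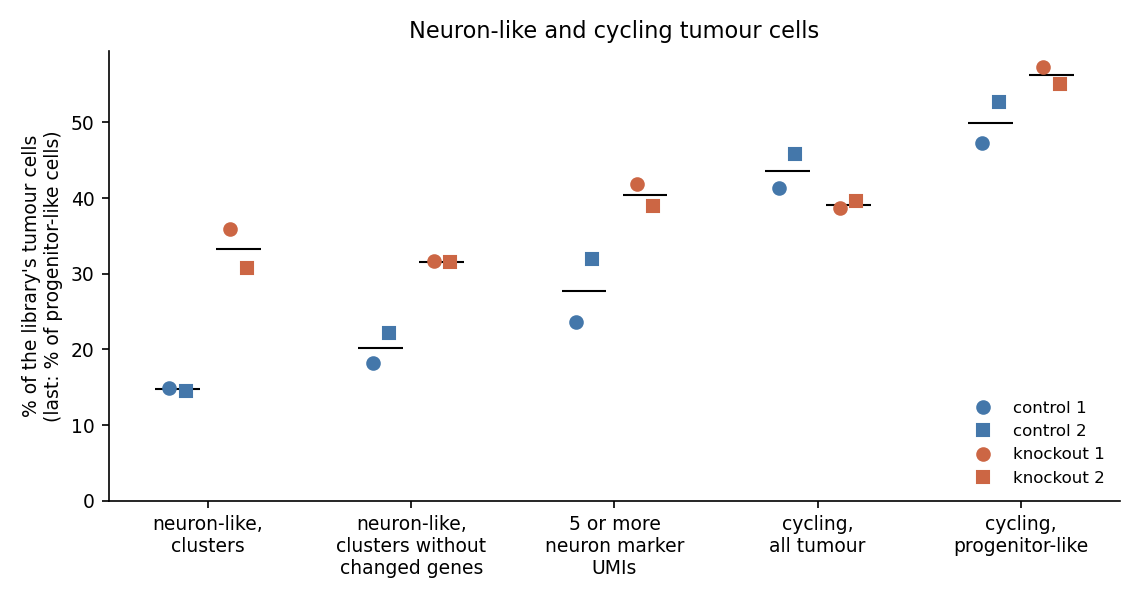
Shares of tumour cells in percent, 1 point per library, for neuron-like and cycling cells. Neuron-like cells lie at 14.9% and 14.5% in controls and at 35.9% and 30.7% in knockouts.

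The blood-tumour barrier was addressed through endothelial-like cells, of which the libraries held 31, 40, 38 and 3. Gsta4, a glutathione transferase that clears lipid peroxidation products, rose 11.4-fold, from 72.8 ± 3.61 to 806 ± 170 CPM (SD, n = 2 each). Sox18, which acts in vessel development and barrier formation, rose 6.89-fold, from 21.3 ± 1.79 to 123 ± 52.1, and Nxpe4, a secreted protein of little known function, rose on 0, 1, 45 and 1 UMIs. Hebp1, a haem-binding protein, fell, on 45, 65, 3 and 0 UMIs in control 1, control 2, knockout 1 and knockout 2. The tight junction gene Cldn5 (0.22, SE 0.394), the lipid transporter Mfsd2a (0.43), the glucose transporter Slc2a1 (0.76), the efflux pump Abcb1a (0.48) and the WNT-dependent genes Axin2 (-0.00), Lef1 (0.18) and Apcdd1 (0.18) did not pass, and Plvap, a marker of leaky vessels, had 0, 0, 2 and 0 UMIs.

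By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4 of 6487 genes changed in endothelial-like cells: Gsta4 (ENSMUSG00000032348, chromosome 9, 78182774 to 78209349) with a log2 fold change of 3.51 (SE 0.356, adjusted p = 0.00169), Hebp1 with -4.66 (SE 0.577, adjusted p = 0.00761), Nxpe4 with 5.56 (SE 0.786, adjusted p = 0.0185) and Sox18 with 2.78 (SE 0.400, adjusted p = 0.0185). Genes with the next small p-values, not past the threshold, included Ackr3 (3.14), H2-T23 (3.14), Cxcl1 (-2.14), Apoe (1.98) and Cwc22 (-2.15). Camera with its preset correlation called 4 of 20 lists: oxidative phosphorylation down (adjusted p = 1.62e-05, lower in 26 of 28) and endothelial barrier and transport (1.82e-05, higher in 25 of 31), G2M phase (0.0126, higher in 18 of 23) and neural stem cells (0.0258, higher in 10 of 11) up. These had an adjusted p of 0.618 with an estimated correlation, and adjusted over the list alone 0, 1, 2 and 0 members passed. Their members with the smallest p were Uqcrq (-1.24) and Atp5g1 (-1.14), Sox18 and, 2.82-fold higher, Marveld2, Top2a (2.35) and Ube2c (1.99), and Id2 (0.92) and Hes1 (-0.78), of which Sox18 alone passed. Fry called the p53 and DNA damage list (adjusted p = 0.0207 by limma). The count of changed genes was 5 without control 1, 62 without knockout 1 and, by edgeR, 0 without control 2 or without knockout 2, under the strict cell filter, with thinned sums or without the low-count filter; with all libraries 492 genes had an unadjusted p below 0.05, and DESeq2 called 1. Sox18 missed the threshold without any one library, Gsta4 (3.37) and Nxpe4 (4.63) also without control 1, and Hebp1 (-8.26) also without knockout 1. Without knockout 1 the G2M list had an adjusted p of 0.896 by camera, and Top2a and Ube2c turned to -5.68; it was 0.198 without control 2, and the neural stem list had 0.354 without control 1 and 0.418 without knockout 2.

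Whether the knockout effect differed between tumour and endothelial-like cells was tested as an interaction. Gsta4 fell in tumour cells (-2.81, adjusted p = 0.00852 by edgeR) and rose in endothelial-like cells, a difference of 6.38 on the log2 scale (SE 0.373). The lipoprotein gene Apoe differed by 2.67 (SE 0.322), with -0.73 in tumour cells, and the matrix proteoglycan gene Dcn by 3.85 (SE 0.525). Apold1, an endothelial stress gene, differed by -2.77 (SE 0.401), with 2.42 in tumour cells, and the noncoding RNA Meg3 by -2.40 (SE 0.349). Further differences lay in Mmrn2 (4.03), Apod (2.31), the TAZ gene Wwtr1 (2.03) and Notch1 (1.99). Others lay in S100a6 (2.47), Ccn1 (2.08), Col4a5 (3.65), Top2a (2.83), Col3a1 (1.92) and Fbln1 (2.92). Col3a1 and Dcn were both fibroblast markers here, and whether the cells that held Dcn also gave other differences was not tested. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 47 of 14012 genes differed, 40 higher and 7 lower in endothelial-like cells (without knockout 1, 6 higher and 117 lower of 123), with adjusted p of 3.37e-61 for Gsta4, 7.61e-13 for Apoe, 1.12e-09 for Dcn, 1.58e-08 for Apold1 and 1.81e-08 for Meg3. Camera called 6 of 22 lists at the preset correlation: oxidative phosphorylation lower (adjusted p = 4.87e-08) and G2M phase (5.45e-05), endothelial barrier (6.60e-05), neural stem cells (4.59e-04), WNT targets (0.0273) and YAP and TAZ targets (0.0273) higher in endothelial-like cells, and 0 with an estimated correlation, whose adjusted p were 0.7002 to 0.888 for these lists. At the preset correlation YAP and TAZ targets lost the call without control 1 (adjusted p = 0.1595), control 2 (0.1499) or knockout 1 (0.217), WNT targets without control 2 (0.525) or knockout 2 (0.1005) and without the low-count filter (0.0730), G2M phase without control 2 (0.264) or knockout 1 (0.830), and neural stem cells without knockout 2 (0.0620). The count of genes was 17 without control 1, 5 without control 2, 123 without knockout 1, 108 without knockout 2 and 31 without the low-count filter. Dcn had 45, 2, 543 and 0 UMIs in the endothelial-like cells of control 1, control 2, knockout 1 and knockout 2. The knockouts thus disagreed, and within endothelial-like cells its adjusted p was 0.455 by edgeR. The p-values of the interaction rest on a spread shared across genes. They do not measure how far the replicates of a single gene disagree, which limits the 47 calls too.

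**Figure D5:**
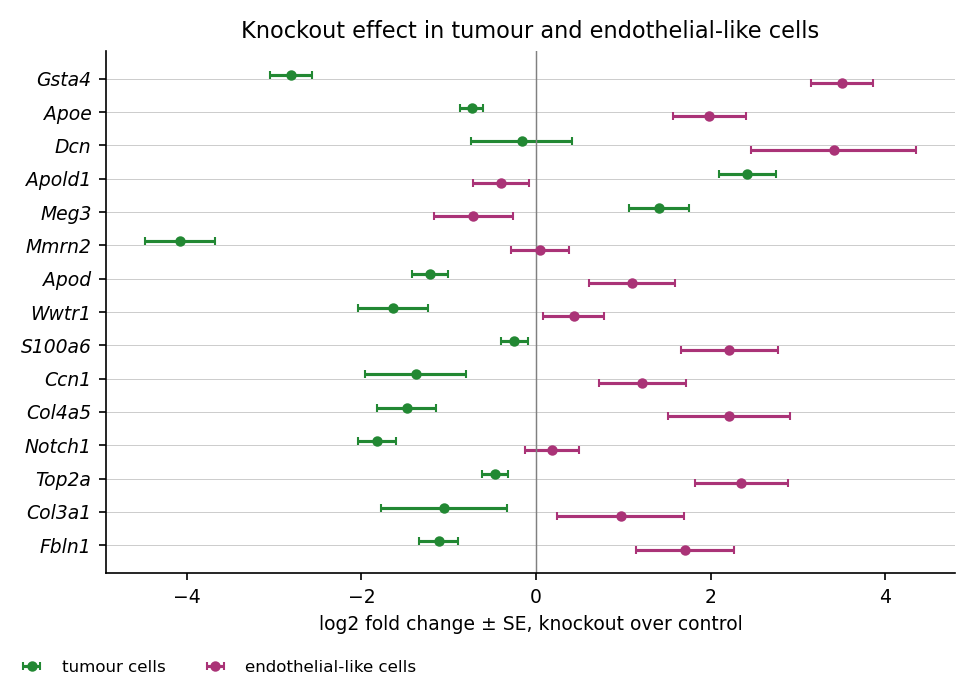
Log2 fold change, knockout over control, in tumour cells and in endothelial-like cells for the genes with the smallest p of the interaction, with standard errors. Gsta4 lies at -2.81 in tumour cells and at 3.51 in endothelial-like cells.

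Other cell types were compared to see which carried an effect of the knockout. In microglia-like cells the MHC class II genes H2-Aa and H2-Ab1, which present antigen to T cells, fell from 206 ± 14.4 to 21.4 ± 8.32 and from 238 ± 7.71 to 28.7 ± 5.60 CPM (SD, n = 2 each), and Rnf121 fell by 2.99 on the log2 scale. Few of the 139, 216, 187 and 21 cells held the class II genes: H2-Aa lay in 5, 14, 4 and 2 cells of control 1, control 2, knockout 1 and knockout 2 and H2-Ab1 in 8, 18, 15 and 4. In oligodendrocyte precursor-like cells the immediate early genes Fosb (1.89), Fos (1.15), Nr4a1 (1.27) and Klf2 (1.01) and the cytokine signalling inhibitor Socs3 (1.92) rose. So did Mycl (2.24), Fgfbp3 (2.23), Gsx1 (2.13) and Id2 (1.01), while Gsta4 (-3.70), the nucleotide kinase Tk1 (-3.69), the histone gene Hist1h1d (-3.41) and Fabp7 (-0.65) fell. In oligodendrocyte-like cells the mitotic genes Ube2c (-5.22), Tpx2 (-3.96), Cenpf (-3.11), Top2a (-2.25) and Hmgb2 (-2.19) fell with Tbata (-4.48), the WNT inhibitor Sfrp1 (-2.40) and Vim (-2.21), and Ccp110 (2.25), Tmem229a (2.23), Prr18 (2.20) and Egr1 (1.45) rose. Sfrp1 is also a granule-lineage progenitor marker, and Tbata was among the leading genes of a cluster of tumour cells. Carried tumour RNA may therefore share in these 2 falls.

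By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 58 of 9436 genes changed in oligodendrocyte precursor-like cells, 60 of 5473 in oligodendrocyte-like cells, 3 of 8514 in microglia-like cells and 0 of 7312 in astrocyte-like cells, where 471 had an unadjusted p below 0.05; DESeq2 called 32, 28, 9 and 4. H2-Aa had an adjusted p of 0.0171, Fosb 7.15e-05 in precursors and Hmgb2 0.00177 in oligodendrocyte-like cells by that edgeR test. Camera with its preset correlation called G2M phase down in astrocyte-like (adjusted p = 1.89e-33, lower in 29 of 30), precursor-like (3.44e-25, 47 of 48), oligodendrocyte-like (2.52e-11, 17 of 21) and microglia-like cells (5.55e-05, 31 of 41). S phase was down in the same classes (6.10e-07, 1.63e-04, 0.0290 and 2.85e-07). With an estimated correlation neither held, the adjusted p of G2M phase being 0.885, 0.894, 0.464 and 0.748 in the same order and that of S phase 0.885, 0.894, 0.521 and 0.748. It also called SHH targets down in oligodendrocyte-like cells (4.89e-05), hypoxia and glycolysis up in astrocyte-like (0.0218) and microglia-like cells (0.00666), immediate early genes up in precursor-like (1.60e-11) and microglia-like cells (0.0334), and interferon and MHC class I up in microglia-like cells (1.84e-06). The smallest adjusted p with an estimated correlation was 0.341, for immediate early genes in precursor-like cells. Adjusted over the list alone, G2M phase held 18, 6, 11 and 0 members in the order above, immediate early genes 9 in precursor-like cells, interferon 2 and SHH targets 5. With doublets kept, Cenpf and Top2a turned to 0.0410 and 0.0792 in oligodendrocyte-like cells and the 3 genes of microglia-like cells missed the threshold, as they did without control 1 or without control 2. Every named gene of precursor-like cells missed the threshold without control 1, without control 2 and without knockout 1, and without knockout 2 all but Fosb and Fos did. In oligodendrocyte-like cells Cenpf, Egr1, Tmem229a, Top2a and Vim missed it without control 1, Cenpf, Prr18, Tmem229a, Tpx2 and Vim without control 2, and Ccp110, Tmem229a and Tpx2 without knockout 1. Leaving out control 1, control 2, knockout 1 or knockout 2, in that order, edgeR called 44, 81, 58 and 66 genes in astrocyte-like cells, 80, 79, 186 and 170 in oligodendrocyte-like cells, 0, 0, 523 and 128 in microglia-like cells (357 and 209 at an unadjusted p below 0.05 where 0) and 0, 0, 0 and 9 in precursor-like cells (587, 385 and 918 where 0). Without the low-count filter it called 84, 215, 151 and 0 in the same order of classes, the 0 with 1079 at an unadjusted p below 0.05, and with doublets kept 8 in oligodendrocyte-like and 54 in precursor-like cells. The summed count of 121 genes was 767 without knockout 1 and 373 without knockout 2, and so hides moves in opposite directions.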

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

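Except for the tests of a response of all cells, of mixed droplets and of fewer cycling glia, the tests of explanations given here were chosen only after the result was seen, as was the comparison of tumour with endothelial-like cells.

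For 5 genes the knockout effect differed between endothelial-like and tumour cells by the test of the difference itself. The differences, endothelial-like minus tumour on the log2 scale, were 6.38 for Gsta4, 2.67 for Apoe, 3.85 for Dcn, -2.77 for Apold1 and -2.40 for Meg3. The endothelial-like side rests on 3 cells in knockout 2, and the p-values of that test do not measure disagreement between replicates of a single gene. Dcn, a fibroblast gene, had 543 UMIs in 4 of the endothelial-like cells of knockout 1 and 0 in knockout 2. No explanation was tested for these 5 genes.

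The sex marker genes were left out when genes were ranked. Ddx3y had 69.5 CPM in knockout 1 and 0 in control 1, control 2 and knockout 2, and Xist had 0.186 CPM in knockout 1. Sex was tested as the whole cause of the 559 changed genes in tumour cells: without knockout 1 the median ratio of their log2 fold changes to those with all libraries was 0.984, and 19 of the 559 lie on X or Y. Few and deep cells in knockout 2 were tested likewise, with a ratio of 1.01 without that library. In thinned sums 72.3% of the calls were kept, and with equal cell numbers 262 of the 559 were. Of the 559 calls 82 were made again without knockout 1 and 149 without knockout 2, with fewer libraries in each fit. The larger share of neuron-like cells was tested within progenitor-like cells, with a ratio of 0.934; that larger share itself rests on 1 cluster, and the difference was 1.54 points with 6 or more neuron markers. The ratios were taken over genes called with all libraries, a call that favours genes on which the knockouts agree. Ratios near 1 without either knockout were therefore largely built in. Progenitor-like cells held most tumour UMIs, 48196388 of 64127889 in knockout 1, so their ratio was built in too, in part. The values show that the called genes moved alike in each knockout and within progenitor-like cells. They cannot decide how far each of the 3 shaped the calls, and a part in single genes stays open.

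Of 322 changed tumour genes tested in microglia-like cells, 52 moved there by 1 log2 unit or more the same way, and 5 the opposite way. Snhg6, Rnf121, Apoo, Cwc22 and Hes1 were among the 52. Tumour RNA carried into microglia-like cells was argued against as the source of most UMIs of these genes there, since the 52 genes reached a median of 73.2% of their tumour level, 9.69 times the 7.56% of granule-lineage markers. To be picked, a gene had to be measured and to shift in microglia-like cells. Levels were taken in the group that was higher in tumour cells. Both choices raise that share, so a part of carried RNA, and its part in single genes, stays open. In oligodendrocyte precursor-like and astrocyte-like cells 97.7% of the 52 moved the same way, against 67.4% and 66.3% of genes not called. The 52 were picked for a shift in microglia-like cells of the same libraries, which favours such agreement. Of all tumour calls tested in precursor-like cells, 87.9% moved the same way. A response of all cells and a genetic background that differs between the genotypes both predict agreement in precursor-like and astrocyte-like cells. So does carried tumour RNA in these 2 classes, where granule-lineage markers stood at 25.7% and 42.5% of the level in cycling tumour cells even in control cells with few cycling UMIs. Background variants linked to a locus would cluster, and 3.85% of the genes lay within 1 Mb of another, with 8.99% of 10000 expression-matched draws having fewer. A mixed background need not cluster, so it cannot be told apart from the genotype in these animals, and both may contribute.

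Genes of cycling were lower in glia of the knockout libraries by camera (limma) at its preset correlation. With an estimated correlation the G2M list had an adjusted p of 0.885 in astrocyte-like, 0.894 in precursor-like and 0.464 in oligodendrocyte-like cells, and with doublets kept Cenpf and Top2a turned to 0.0410 and 0.0792 in oligodendrocyte-like cells. A smaller amount of tumour RNA carried into glia would lower granule-lineage markers alike, but the cycling markers fell further by a median difference of -1.76 over 3 classes: -3.26 in astrocyte-like, -1.76 in oligodendrocyte-like and -0.63 in precursor-like cells, the last within the spread of its markers. In tumour cells, however, most G2M genes were lower too, while granule-lineage markers moved both ways. Nrn1, Tubb3, Cntn2 and Gabra6 rose there, and Gli1 and Grin2b fell. Carried RNA could therefore give a part of these differences, and how large a part was not tested. In oligodendrocyte-like cells the granule-lineage markers had a median log2 fold change of -0.775. The marker Sfrp1 and the tumour cluster gene Tbata fell past the threshold in oligodendrocyte-like cells, so carried RNA stays open in that class too. In controls, 95 of 616 glial cells held 93.2% of the cycling UMIs, which fewer cycling glia and mixed droplets would both give, so that value does not decide between them. After thinning, 42 of 187, 29 of 213, 13 of 132 and 2 of 22 precursor-like cells of control 1, control 2, knockout 1 and knockout 2 had 2 or more cycling UMIs. In astrocyte-like cells it was 7 of 77, 10 of 50, 4 of 96 and 0 of 5, and in oligodendrocyte-like cells 3 of 24, 4 of 45, 1 of 57 and 0 of 8, though in unthinned astrocyte-like cells 14 of 80, 21 of 50, 20 of 109 and 0 of 6, and in unthinned oligodendrocyte-like cells 6 of 25, 9 of 46, 2 of 60 and 3 of 9. Droplets holding a glial and a tumour cell stay open as well: granule-lineage markers in those 95 cells stood at 38.7% of the level in cycling tumour cells, but at 30.3% in the other glial cells, which made the bound of 30% set for that test too low. By class the 2 levels were 25.3% and 25.7% in precursor-like, 47.6% and 24.1% in oligodendrocyte-like and 55.5% and 42.5% in astrocyte-like cells. Median UMIs per cell were 6074 against 4379, 16205 against 6103 and 15217 against 6351 in the same order, and precursor-like cells made 69 of the 95.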

How the results depend on the processing

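Alternatives that kept the unnamed cluster, changed the Leiden resolution for the neuron-like difference, set neuron-like cells by marker UMIs or by 6 neuron markers, or clustered tumour cells without changed genes, and all alternatives for endothelial-like cells and the interaction, were tests chosen only after the result was seen. With a library left out, a lone sample in an arm is assumed to vary like the other groups. Where no cause is given, the cause was not tested.

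The 559 genes of tumour cells became 1623 by DESeq2, 156 without the low-count filter, 296 with equal cell numbers and 118 to 746 with a library left out. The 146 of progenitor-like cells became 991, 463 and 313 in the same order, and 2 to 534. The 477 of neuron-like cells became 1444 without the low-count filter, 130 under the strict cell filter and 0 to 356 with a library left out, the 0 by edgeR without knockout 2, with 1699 at an unadjusted p below 0.05. The 4 of endothelial-like cells became 1 by DESeq2, 15 with equal cell numbers, 0 by edgeR without the low-count filter, under the strict filter or with thinned sums, and 0 to 62 with a library left out; 492 had an unadjusted p below 0.05 with all libraries. The 121 of the other classes became 73 by DESeq2, 450 without the low-count filter, 62 with doublets kept and 124 to 767 with a library left out. These sums hide opposite moves: without the low-count filter precursor-like cells went from 58 to 0 by edgeR (1079 at an unadjusted p below 0.05), while astrocyte-like cells went from 0 to 84, microglia-like from 3 to 151 and oligodendrocyte-like from 60 to 215. With doublets kept oligodendrocyte-like cells had 8 and precursor-like cells 54. No value under the strict filter is given for these, since 3 of the 4 classes had fewer than 5 cells in a library.

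With the replicate numbers as a block (replicate block), the counts were 1121 in tumour, 140 in progenitor-like (107 of the 146 kept), 1157 in neuron-like, 26 in endothelial-like and 621 in the other classes, and Piezo2 stood at -2.39. The correlation of same-numbered deviations was 0.0955.

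Camera's 6 lists in tumour cells became 0 with an estimated correlation and 0 by fry, and 4 to 8 with a library left out; the 4 of endothelial-like cells became 0, 1 and 3 to 6. The 47 genes of the interaction became 31 without the low-count filter and 5 to 123 with a library left out. Piezo2 ranged from -2.63 to -1.99 with a library left out, and missed the threshold without knockout 1 (-2.42) or knockout 2 (-2.31). Of the class shares, 0 passed by edgeR, with 1 at an unadjusted p below 0.05, 1 passed at Leiden resolution 0.5 and 2 under the strict filter. The neuron-like difference of 18.6 points was 22.7 at resolution 0.5, 15.1 at resolution 2, 15.7 under the strict filter, 12.6 by marker UMIs, 1.54 with 6 or more neuron markers, 11.4 without changed genes, where the naming rule changed too, and 16.0 to 21.2 with a library left out. The cycling difference of -4.45 was 1.13 in unthinned cells, and -6.71 to -2.18 with a library left out.

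Some genes that had not passed changed sign; ranges are those with a library left out. In tumour cells Ptch1 ranged from -0.30 to 0.0902 (0.0902 without control 1, 0.00905 without knockout 1), Neurod1 from -0.0698 to 0.299 (below 0 without control 1 and, at -0.0697, without knockout 2; -0.10 under the strict filter), Axin2 in tumour cells from -0.314 to 0.40 (above 0 without control 2 and, at 0.11, without knockout 1; 0.00562 without the low-count filter, 0.0523 with the replicate block) and Vegfa from -0.0106 without knockout 1 to 0.968. Outside the tumour, Cldn5 in endothelial cells ranged from -0.30 without knockout 2 to 0.584, Lef1 from -0.285 without knockout 2 to 1.05 (-0.12 without control 1), Apcdd1 from -0.0109 without control 2 to 0.247, Top2a from -5.68 without knockout 1 to 2.56, Ube2c from -5.68 without knockout 1 to 2.20 and Axin2 in endothelial cells from -0.197 to 0.28 (above 0 at 0.15 without control 1 and without knockout 1; 0.0621 by DESeq2, 0.00226 without the low-count filter, 0.00900 without cell filter, 0.0962 with doublets kept). In endothelial cells Rgs5 stood at 0.45 under the strict filter and Fn1 at 0.15 with equal cell numbers. The called genes Cenpf and Top2a of oligodendrocyte-like cells turned to 0.0410 and 0.0792 with doublets kept. Of 629 values of called tumour genes 494 kept the call and 135 missed it, all in the same direction. The 3 endothelial-like cells of knockout 2 limit all results of that class.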

Other observations

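Cd74, H2-Eb1 and the comparisons between classes were chosen only after the result was seen, as was the test of endothelial-like cells; the other tests and the rule that named Sox18, Rnf121, H2-Aa and H2-Ab1 were set earlier.

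In microglia-like cells the invariant chain gene Cd74, which loads MHC class II molecules, had 518, 852, 109 and 43 UMIs in control 1, control 2, knockout 1 and knockout 2, and H2-Eb1, a class II beta chain, had 186, 248, 41 and 0. These lay in few cells, 21, 40, 24 and 6 for Cd74 and 3, 11, 3 and 0 for H2-Eb1, of 139, 216, 187 and 21. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Cd74 had a log2 fold change of -2.51 and an adjusted p of 0.0520, and H2-Eb1 -3.17 and 0.240, so neither passed. H2-Aa and H2-Ab1, of the same complex, did.

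Sox18 rose in tumour, progenitor-like, neuron-like and endothelial-like cells, by 2.76, 2.71, 3.46 and 2.78 on the log2 scale. Rnf121 fell by 2.70 in tumour cells and by 2.99 in microglia-like cells. Among genes called in tumour cells, 19 were also called, all the same way, in oligodendrocyte precursor-like cells, and 12 in oligodendrocyte-like cells, 11 of them the same way. The same libraries gave both sides, and 66.6% and 66.7% of all genes tested in both moved the same way.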
